A study of Mus musculus with 12 samples.

How the data were processed

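The samples were tumors or normal glandular stomach of mice kept under specific pathogen-free conditions and aged 40 to 50 weeks. Biotin-labelled cRNA was made from 250 ng of total RNA and hybridized to Affymetrix arrays, per the labels' protocols. The deposited values are intensity on a linear scale, 1 column per array, made by the authors with MAS5, per the submitters' processing notes. The MAS5 version and settings are not given in the sources used here. From the values, the mean of each array after trimming 2% at each end lay between 497.2 and 497.8, which shows that arrays had been scaled alike, and 0 values were below 0. Groups and replicate numbers were taken from the sample titles, 3 mice per group, and 0 columns of samples were left unused.

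The table held 45037 probe sets. By the platform annotation, 34945 had 1 gene symbol, 932 several and 9160 none, and 34741 of those with 1 symbol were matched by gene ID to the RefSeq gene table of assembly GRCm38.p6, which was used for current names and for which chromosome a gene lies on. The annotation names no genome build, so no coordinates are given. Of 18193 genes with a probe set of their own, each was represented by the probe set with the highest mean log2 value over the 12 arrays. Genes were kept where at least 3 of 12 arrays exceeded 58.3, the 40th percentile of all values, which left 13581 genes.

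Values were transformed as log2(value + 18.4), the pseudocount being the 20th percentile of all values, with no further normalization between arrays. Folds on this scale understate the change of dim genes. All 12 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with an intensity trend), which gives 1 shared estimate of the spread. Tests were two-sided (an exact permutation test of 3 against 3 arrays cannot go below 0.1), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 applied to unrounded values. Gene lists of cell types and pathways, written before the data were examined, held 442 genes, of which 362 were tested, in 37 lists with at least 3 tested members. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. A rotation test, fry, which keeps the correlation between genes, was also run. It was not in the plan, and its p-values are given without adjustment over lists. Fry asks whether the genes of a list changed in one direction, not whether they changed more than other genes.

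Named genes follow a rule written before the data were examined. It takes, per main comparison, the 10 genes with the largest log2 difference in each direction among those past the threshold with non-overlapping arrays (names that are only accessions or clone numbers left out). It adds up to 4 members per list, those past the threshold with the largest difference or, where none passed, the 2 with the smallest p, and the genes of the design: transgenes, the knocked-out gene, genes the study is known for, strain control genes and sex-linked genes. Of these, the text names the largest changes, the members of lists that passed, examples from 4 lists that did not pass, which were chosen after their values were seen, and the design genes, with strain control and sex-linked genes only where they bear on a comparison. Comparisons, tests other than fry and most alternatives were also fixed before the data were examined.

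The steps were tested on simulated data shaped like the labelled-knockout and Gan arrays, with 13581 genes of which 200 were changed. At a log2 difference of 1, 70 of 100 changed genes were recovered, and at 2, 94 of 100, with 10 false calls. Between the real groups 3 genes were called, and the adjustment is stricter where fewer genes change. These shares may thus overstate the recovery in that comparison. A list shifted by 0.5 was found, and 0 of 36 other lists were called. The simulated noise was independent between genes, so this does not test list calls where the genes vary together. The interferon response list, for one, had an estimated correlation of 0.535.

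Alternatives covered the pseudocount, the filter, the normalization, the choice of probe set, the intensity trend, array weights, the arrays in the fit, the replicate number as a block, each array left out in turn, and the camera correlation. A sex term, read from Xist and Y-linked signals, was added after the data were seen. A planned check of RNA quality from 3 prime over 5 prime control probe sets was not run, because the values used here hold 0 control probe sets.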

Results

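The series measured gene expression in mouse stomach on 12 Affymetrix arrays, 1 array per mouse, in 4 groups of 3 mice aged 40 to 50 weeks. Gan mice carry transgenes for Wnt1, a ligand of the Wnt pathway, and for Ptgs2 and Ptges, the enzymes that lead to prostaglandin E2, and develop gastric tumors. The groups were normal glandular stomach of C57BL/6 mice (WT), tumors of C57BL/6 Gan mice (Gan), tumors of C57BL/6 Gan mice labelled as TNF knockout (here labelled-knockout tumors), and tumors of Gan mice on the BALB/c strain. The arrays were scaled alike, with trimmed mean signals of 497.2 to 497.8 and medians of 88.1 to 121.8. The number of arrays, 3 per group, limits the precision of every value. Signals are given as mean ± SD (n = 3), and log2 differences as estimate ± SE on the log2(signal + 18.4) scale, which understates the change of dim genes. Of 13581 genes tested, limma called 4639 between Gan tumors and WT, 3 between labelled-knockout and Gan tumors, and 197 between BALB/c and Gan tumors.

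The first comparison asked how the tumors differed from normal stomach. In Gan tumors 8 of 9 parietal cell, 5 of 6 chief cell, 8 of 10 hormone cell and 10 of 10 smooth muscle genes fell. Of mucous neck and metaplasia genes 8 of 8 rose, as did 5 of 12 antimicrobial genes and 14 of 19 genes of cell division, while 1 of the 19 fell. Each of these lists passed camera at a preset correlation, and none with an estimated correlation (adjusted p from 0.23 to 0.51). By the rotation test fry their unadjusted p ranged from 2.6e-07 for mucous neck and metaplasia genes to 0.0021 for genes of cell division. Reg3b and Reg1, secreted lectins of injured and inflamed gut, rose from 47.2 ± 22.4 to 14200 ± 2300 and from 102 ± 18.2 to 24800 ± 399, log2 differences of 7.80 ± 0.32 and 7.70 ± 0.23. Pgc, the precursor of a pepsin, fell from 26500 ± 5660 to 316 ± 254, a log2 difference of -6.54 ± 0.87. Atp4a, the catalytic subunit of the gastric proton pump, fell from 27600 ± 2330 to 649 ± 346, a log2 difference of -5.49 ± 0.63.

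By limma with Benjamini-Hochberg adjustment, 2280 genes were higher and 2359 lower in Gan tumors than in WT, and 5949 genes had an unadjusted p under 0.05. The even split depended on scaling, as median centring gave 3503 higher and 1640 lower. The arrays of the 2 groups did not overlap for 48% of the genes, where chance gives 10%. Among the 10 genes with the largest rise, the chloride channel Cftr rose by 7.31 ± 0.49, the tight junction protein Cldn2 by 7.21 ± 0.70, Wfdc18 by 7.06 ± 0.67, Reg3g by 6.54 ± 0.63, the potassium channel subunit Kcne3 by 6.49 ± 0.45 and Lrg1 by 5.74 ± 0.44. Among those with the largest fall, log2 differences were -6.86 ± 0.67 for Kcne2, the potassium channel subunit of parietal cells, -6.47 ± 0.66 for Hamp2, -6.26 ± 0.69 for the cholecystokinin receptor Cckar, -6.25 ± 0.64 for Tnni3, -6.20 ± 0.53 for Gpm6a, -6.15 ± 0.67 for Tmed6, -5.93 ± 0.53 for Pdia2 and -5.84 ± 0.68 for lipoprotein lipase, Lpl. Xist, expressed from the inactive X chromosome of females, was lower by -7.48 ± 1.36, and the Y-linked genes Eif2s3y, Uty and Kdm5d were higher by 6.21 ± 1.21, 4.80 ± 0.87 and 4.47 ± 1.01. Xist was high and the Y-linked genes low in 3 of 3 WT arrays, 0 of 3 Gan arrays, 1 of 3 labelled-knockout arrays and 0 of 3 BALB/c arrays, so the sex of the mice followed the groups in this comparison. With sex as a term in the model, which rests on the 1 labelled-knockout array with high Xist and was added after the data were seen, 698 genes were called. With that term Pgc was at -2.81 (adjusted p = 0.11), Atp4a at -3.62 (0.059) and Lpl at -4.10 (0.063), and the chief cell (mean -1.64, adjusted p = 0.083), exocrine pancreas (-1.36, 0.057) and proliferation (0.25, 0.057) lists did not pass.

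The transgenes and the genes the study is known for were measured next. Ptgs2 rose from 43.7 ± 20.3 to 3130 ± 1190, a log2 difference of 5.64 ± 0.66. Its other probe set read 204 ± 54.4 in WT and 265 ± 234 in Gan tumors. Ptges rose by 1.14 ± 0.26 (limma adjusted p = 0.0057), from 168 ± 52.2 to 397 ± 128, a call that was lost when all probe sets of the gene were averaged (log2 difference 0.53, adjusted p = 0.14) and with the sex term (0.82, 0.4), with adjusted p from 0.0011 to 0.4 over the alternatives. Wnt1 was too dim to be tested, with 41.1 ± 11.3 in WT and 45.9 ± 29.2 in Gan tumors. Noxo1, the organizer subunit of the NOX1 complex, rose from 29.6 ± 17.7 to 1870 ± 150, a log2 difference of 5.35 ± 0.32 (limma adjusted p = 8.7e-07). Gna14, a G protein alpha subunit, rose from 410 ± 206 to 1040 ± 133, by 1.40 ± 0.36 (limma adjusted p = 0.0099), and did not pass with the sex term (1.90, adjusted p = 0.13). Both genes were listed because of the study, so their direction here is no independent evidence. Tnf read 79.2 ± 44 in Gan tumors and 32.9 ± 32.1 in WT, a log2 difference of 0.98 ± 0.48 that did not pass (limma adjusted p = 0.14) but did without WT replicate 2 (1.45, 0.037) or Gan replicate 2 (1.42, 0.0469).

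Of 37 gene lists tested with camera at a preset correlation of 0.01, 11 passed, 4 higher and 7 lower in Gan tumors, and 0 passed with an estimated correlation. All 8 tested mucous neck and metaplasia genes rose (camera adjusted p = 1.1e-07, or adjusted p = 0.23 with an estimated correlation), among them Cftr, Dmbt1 by 3.75 ± 0.23, the water channel Aqp5 by 3.19 ± 0.32 and Wfdc2 by 2.83 ± 0.40. Of 12 antimicrobial genes 5 rose (camera adjusted p = 0.0011, or adjusted p = 0.51 with an estimated correlation), among them the iron-binding protein Ltf by 5.15 ± 1.00 (5.84 with the sex term, adjusted p = 0.11). Of 19 proliferation genes 14 rose and 1 fell (camera adjusted p = 1.0e-04, or adjusted p = 0.51 with an estimated correlation). The replication helicase subunit Mcm6 rose by 1.20 ± 0.14, Top2a by 1.10 ± 0.19 and Cdk1 by 1.08 ± 0.16, and the one that was lower was Foxm1, a transcription factor of the cell cycle, at -1.82 ± 0.36. With the sex term Top2a was at 0.61 (0.31), Cdk1 at 0.74 (0.16) and Foxm1 at -1.73 (0.18), and none of the 3 passed. The fall of Foxm1 was also lost when its probe sets were averaged (-0.45, adjusted p = 0.16, range over the alternatives 0.00054 to 0.18). Of 7 NADPH oxidase genes 2 rose, Noxo1 and the membrane subunit Cyba, the latter by 1.98 ± 0.10. That list stood at the threshold (camera adjusted p = 0.0497, or adjusted p = 0.53 with an estimated correlation), was lost under 3 of the other processing choices and without WT replicate 1 (0.073), WT replicate 3 (0.056) or Gan replicate 1 (0.06), ranged from 0.014 to 0.11 over the alternatives, and holds a gene chosen from the study.

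In the lists that fell, 8 of 9 parietal cell genes were lower (camera adjusted p = 2.7e-06, or adjusted p = 0.39 with an estimated correlation), including the chloride and bicarbonate exchanger Slc26a7 at -5.48 ± 0.48 and Esrrg at -5.31 ± 0.47. Of 6 chief cell genes 5 fell (0.0076, or adjusted p = 0.44 with an estimated correlation), with Cblif, gastric intrinsic factor, at -5.46 ± 0.91, the chitinase Chia1 at -5.15 ± 1.09 and Bhlha15 at -3.24 ± 0.37. With the sex term Chia1 was at -0.70 (adjusted p = 0.82) and Cblif at -2.86 (0.31). Of 10 enteroendocrine genes 8 fell (2.4e-04, or adjusted p = 0.44 with an estimated correlation), with somatostatin, Sst, at -4.79 ± 0.61, chromogranin A, Chga, at -4.17 ± 0.76, the histamine-forming enzyme Hdc at -4.04 ± 0.53 and Slc18a2 at -3.90 ± 0.52. None of these 4 passed with the sex term, Sst at -2.85 (0.11), Chga at -3.37 (0.21), Hdc at -3.19 (0.084) and Slc18a2 at -3.67 (0.059). All 10 smooth muscle genes fell (1.1e-07, or adjusted p = 0.39 with an estimated correlation), with Cnn1 at -4.01 ± 0.42, Myh11 at -3.89 ± 0.50, Des at -3.17 ± 0.47 (-3.13 with the sex term, 0.074) and Actg2 at -3.17 ± 0.43. Of 20 oxidative phosphorylation genes 17 fell (3.1e-09, or adjusted p = 0.39 with an estimated correlation), by less: Ndufa4 was at -1.32 ± 0.15, Uqcrfs1 at -0.95 ± 0.08, Ndufs1 at -0.84 ± 0.09 and Sdhb at -0.81 ± 0.10. Of 16 interferon response genes 7 fell (0.0042, or adjusted p = 0.62 with an estimated correlation), with Iigp1 at -1.75 ± 0.44, Ifit3 at -1.72 ± 0.42, Usp18 at -1.69 ± 0.41 and Gbp2 at -1.62 ± 0.47. With the sex term these 4 did not pass, Iigp1 at -1.83 (0.25), Ifit3 at -0.90 (0.57), Usp18 at -1.94 (0.19) and Gbp2 at -1.21 (0.51). The interferon list mean of WT replicate 2 was 1.5 above the 12-array mean, against -0.08 and 0.15 in the other WT arrays, and the call of Gbp2 was lost without it (adjusted p = 0.083) and without Gan replicate 3 (0.077), with a range of 0.011 to 0.51 over the alternatives. Without WT replicate 2 the list mean went from -1.08 to -0.59 (adjusted p = 0.0475) and Usp18 to -1.12 (0.016). Of 6 exocrine pancreas genes 4 fell (0.015, or adjusted p = 0.35 with an estimated correlation), with Clps at -2.97 ± 0.62, Cel at -2.48 ± 0.54, Cpb1 at -2.25 ± 0.41 and Cela2a at -1.63 ± 0.32. The sex term gave Clps -1.17 (0.57), Cel -1.73 (0.38), Cpb1 -1.50 (0.28) and Cela2a -1.92 (0.1), and none passed. That list was lost with no filter on dim genes (0.12, range over the alternatives 0.0033 to 0.12).

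The other 26 lists did not pass, with camera adjusted p from 0.079 to 0.99. Mean log2 differences were -1.15 for prostaglandin, 0.82 for immediate early, 2.23 for claudins, -2.09 for intestine, -1.22 for pit cell, 0.69 for cytokines and chemokines, 0.26 for Wnt target and 0.46 for NF-kB and TNF response genes. They were 0.53 for matrix protease, 0.85 for mast cell, -0.62 for skeletal muscle, -0.37 for fibroblast and matrix, 0.20 for EGFR ligand, 0.19 for TNF ligand and receptor, -0.43 for MHC class II, -0.05 for endothelium, 0.02 for B and plasma cell, -0.89 for adipocyte and 0.06 for unfolded protein response genes. They were -0.08 for macrophage, -0.86 for squamous forestomach, 0.28 for neutrophil, 0.40 for T and NK cell and 0.09 for nerve and glia genes. The mean was -0.13 for stem and progenitor and -0.09 for glycolysis and hypoxia genes, whose camera direction was upward and whose medians were -0.61 and -0.25. Median centring of the arrays took the median of all genes from -0.01 to 0.17, so list means within that distance of 0 have no settled direction. Squamous forestomach genes varied within groups, with list means of 3.39, 2.01 and -2.38 in the WT arrays and 1.68, 0.68 and -1.92 in the Gan arrays.

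**Figure D1:**
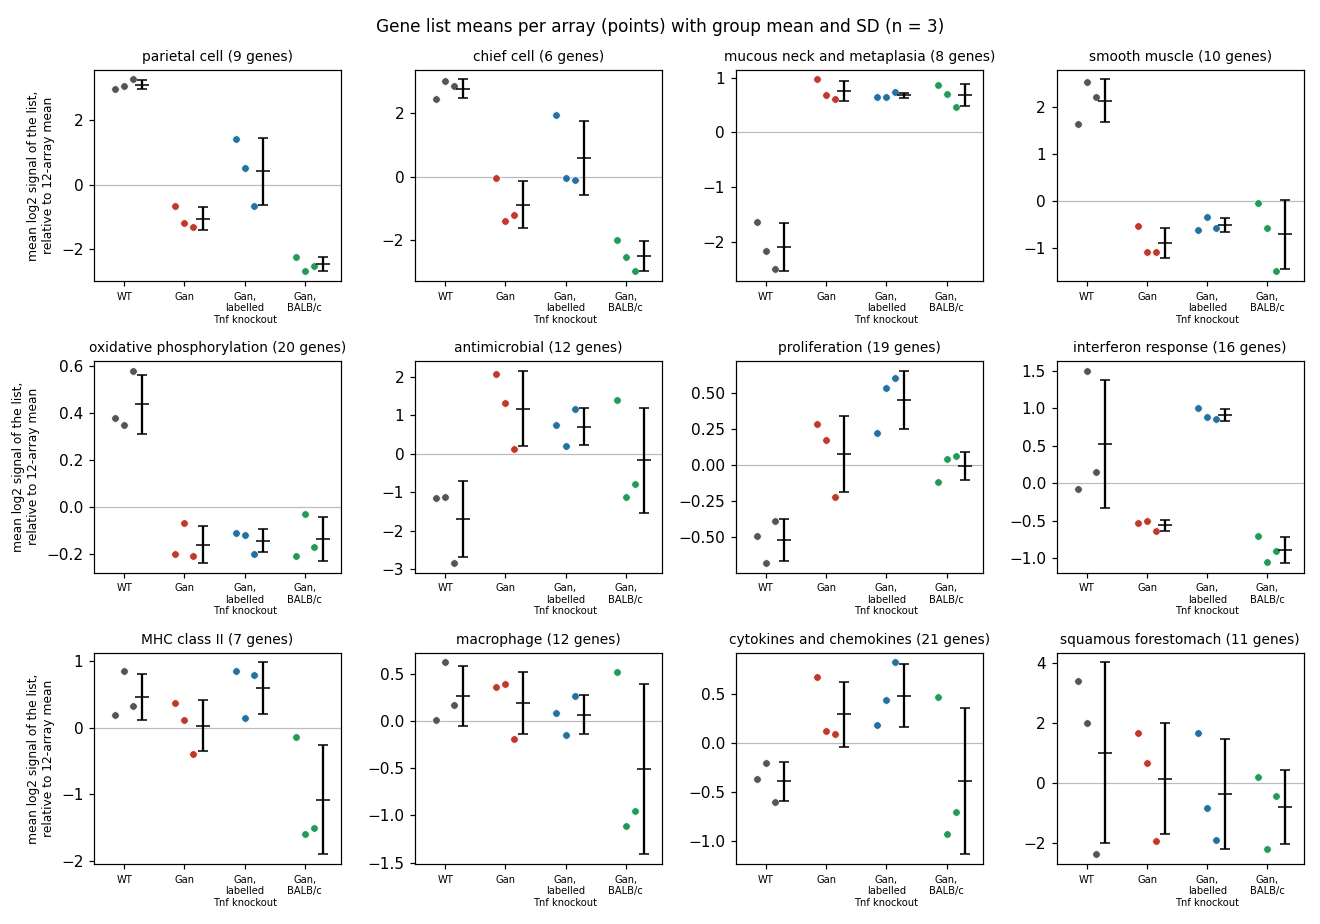
Mean log2 signal of 12 gene lists on each array, relative to the mean over the 12 arrays (vertical axes), by group (horizontal axes); points are arrays, and the bar beside them is the group mean with its SD (n = 3). The interferon response means lie from 0.86 to 1.00 in the labelled-knockout arrays and from -0.64 to -0.50 in the Gan arrays.

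The next comparison set Gan tumors labelled as TNF knockout against Gan tumors. The Tnf probe set read 455 ± 180 in the labelled-knockout arrays and 79.2 ± 44 in the Gan arrays, higher rather than lower, with a log2 difference of 2.33 ± 0.48 that did not pass (limma adjusted p = 0.18). The sources used here do not say which part of the gene was deleted or where the probe set lies, so this signal does not check the label. Interferon response genes were higher as a list, at a mean log2 difference of 1.47 with 16 of 16 positive, and parietal, chief and enteroendocrine genes were also higher as lists. These calls hold at a preset correlation and were lost with an estimated correlation (adjusted p = 0.41, 0.44, 0.44 and 0.69). By the rotation test fry the unadjusted p was 0.0027, 0.019, 0.03 and 0.091. The parietal and chief cell means of single arrays overlapped between the groups. Only 3 single genes passed: Glo1, which detoxifies methylglyoxal, rose from 4740 ± 500 to 9520 ± 496, by 1.01 ± 0.09 (limma adjusted p = 0.002), Tmem151a rose from 18 ± 3.38 to 153 ± 55.5, by 2.19 ± 0.24 (0.0092), and Mmut, methylmalonyl-CoA mutase, was lower at 1000 ± 106 against 1740 ± 141, a difference of -0.79 ± 0.10 (0.02).

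At an unadjusted p under 0.05, 598 genes were higher and 503 lower, and the arrays did not overlap for 15.6% of genes, where chance gives 10%. The count of 3 became 13 without labelled-knockout replicate 3 and 1 without Gan replicate 1 or Gan replicate 2, and Mmut turned to 0.14 (adjusted p = 0.89) when its probe sets were averaged. Without Gan replicates 1 and 2 in turn, Mmut (0.14 and 0.18) and Tmem151a (0.069 and 0.052) did not pass, nor did Mmut without labelled-knockout replicate 2 (0.094). Over the alternatives adjusted p ranged from 0.0071 to 0.89 for Mmut, 0.0028 to 0.075 for Tmem151a and 0.00042 to 0.029 for Glo1. Noxo1 read 803 ± 343 against 1870 ± 150, a log2 difference of -1.30 ± 0.32 with an unadjusted p of 0.0016 that did not pass over all genes (limma adjusted p = 0.31), and Cyba differed by -0.60 ± 0.10 (0.12, or 0.029 with array weights). Gna14 differed by -0.51 ± 0.36 (0.77), Ptgs2 by 0.19 ± 0.66 (0.97) and Ptges by -0.03 ± 0.26 (0.99), and the signs of the last 2 turned under other settings.

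By camera 5 lists passed, all higher in the labelled-knockout tumors, and 0 with an estimated correlation. For the interferon list the adjusted p was 1.7e-18, or adjusted p = 0.41 with an estimated correlation. Of its 16 genes 0 passed over all genes tested, and 12 passed when adjusted over the list alone. The interferon-induced GTPases Igtp and Iigp1 differed by 2.51 ± 0.41 and 2.65 ± 0.44 (limma adjusted p = 0.12 for each). Both passed with median centring (0.0482) and array weights (0.029), and Igtp with only the groups compared (0.018). The parietal cell list had a mean difference of 1.47 (camera adjusted p = 9.0e-07, or adjusted p = 0.44 with an estimated correlation), with 6 of 9 genes past the threshold when adjusted over the list alone, and Kcne2 at 2.93 ± 0.67 (0.27 over all genes, or 0.029 without labelled-knockout replicate 3) and Esrrg at 1.87 ± 0.47 (0.32). The chief cell list had a mean of 1.48 (0.0012, or adjusted p = 0.44 with an estimated correlation), with 3 of 6 past it over the list alone, Pgc at 2.56 ± 0.87 (0.48) and the pepsinogen Pga5 at 1.16 ± 0.33 (0.39). The enteroendocrine list had a mean of 0.98 (8.9e-04, or adjusted p = 0.69 with an estimated correlation), with 0 of 10 past it over the list alone, Sst at 1.69 ± 0.61 (0.52) and Slc18a2 at 1.43 ± 0.52 (0.52). The proliferation list had a mean of 0.37 (1.6e-06, or adjusted p = 0.69 with an estimated correlation), with 1 of 19 past it over the list alone, Foxm1 at 1.62 ± 0.36 (0.23) and Bub1 at 0.57 ± 0.23 (0.57), and its mean was 0.22 without Gan replicate 3 (adjusted p = 0.0031). Labelled-knockout replicate 1, the array with high Xist, had the highest parietal and chief cell means of its group, 1.41 and 1.94, against 0.52 and -0.04 in replicate 2 and -0.67 and -0.10 in replicate 3. Gan replicates 1, 2 and 3 had parietal means of -0.65, -1.18 and -1.32 and chief cell means of -0.03, -1.38 and -1.22. Gan replicate 1 thus lay above labelled-knockout replicate 3 in both lists, and above labelled-knockout replicate 2 for chief cell genes. Without labelled-knockout replicate 1 the chief cell mean difference was 0.81 (adjusted p = 0.044). The other 32 lists did not pass, with adjusted p from 0.056, for nerve and glia genes at a mean of -0.67, to 0.96. The mean was 0.08 for NF-kB and TNF response genes and 0.18 for TNF ligand and receptor genes. For B and plasma cell genes (mean 0.42, median -0.36) and matrix protease genes (mean 0.22, median 0.08) the camera direction was downward. Without Gan replicate 1, 9 lists passed.

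**Figure D2:**
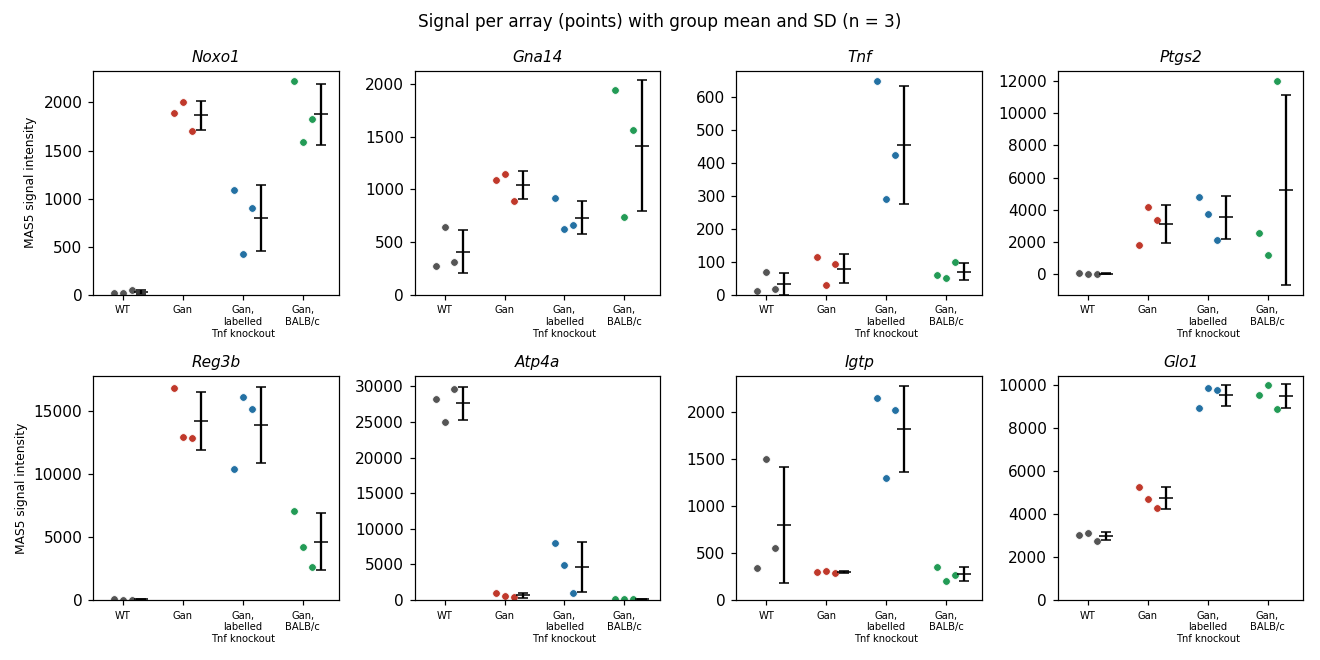
Signal intensity of 8 genes on each array (vertical axes, linear scale), by group (horizontal axes); points are arrays, and the bar beside them is the group mean with its SD (n = 3). Noxo1 averages 1870 in Gan and 803 in labelled-knockout tumors, and Tnf 79.2 and 455.

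The last main comparison set Gan tumors of BALB/c mice against those of C57BL/6 mice. No normal BALB/c stomach was analysed here, so strain and tumor cannot be separated. Muc3, a membrane mucin, rose from 65 ± 24.1 in C57BL/6 to 5740 ± 2010 in BALB/c tumors, by 6.08 ± 0.39. Pdxdc1 was at 301 ± 16.5 against 4890 ± 93.7, a log2 difference of -3.94 ± 0.07. Its other probe sets differed by -2.69, -2.30 and 7.45, so that their average was at -0.37 (adjusted p = 0.38). The antimicrobial lectins Reg3g, Reg3b and Reg1 fell, with log2 differences of -2.98 ± 0.63, -1.72 ± 0.32 and -1.12 ± 0.23 (limma adjusted p = 0.042, 0.025 and 0.041). Noxo1 was at 1880 ± 320 against 1870 ± 150, a difference of 0.00 ± 0.32.

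By limma with Benjamini-Hochberg adjustment, 100 genes were higher and 97 lower, with 1865 at an unadjusted p under 0.05 and non-overlapping arrays for 17.7% of genes, where chance gives 10%. Other genes with the largest rise were Dnah8 by 4.12 ± 0.60, Mndal by 3.21 ± 0.32, the DNA sensor Aim2 by 3.19 ± 0.52, Tmem87a by 2.98 ± 0.19, Ap1s3 by 2.84 ± 0.23, Myh7 by 2.57 ± 0.52, Pm20d1 by 2.52 ± 0.31 and Padi4 by 2.51 ± 0.54. H2-Ea, a class II gene that C57BL/6 mice do not express, rose from 13.3 ± 15.5 to 454 ± 468, by 3.52 ± 0.65 (adjusted p = 0.023). That call was lost without Gan replicate 2 (0.096) or replicate 3 (0.079) and with only the groups compared (0.1). Its other probe sets read 19 ± 2.02 and 17 ± 8.8 in C57BL/6 tumors, and 169 ± 247 and 16.1 ± 3.34 in BALB/c tumors. Pla2g2a differed by -0.44 ± 0.37 (0.64). Those with the largest fall were St6gal2 at -4.53 ± 0.32, Smim38 at -3.52 ± 0.71, Apoa1 at -3.38 ± 0.66, Ly6e at -3.27 ± 0.72, Zfp945 at -2.93 ± 0.48, the mucin Muc4 at -2.93 ± 0.20, Vps52 at -2.91 ± 0.17 and Slc15a2 at -2.84 ± 0.40. When probe sets marked as matching several sequences were left out, Muc4 turned to 1.06 (adjusted p = 0.099), and Vps52 (-0.28, 0.58), Slc15a2 (-1.95, 0.31) and Pm20d1 (1.57, 0.11) did not pass. With averaged probe sets Zfp945 (-0.94, 0.12), Smim38 (-1.88, 0.093) and H2-Ea (1.64, 0.12) did not pass. Of 23 named genes past the threshold, 6 passed under every alternative run: Muc3, Dnah8, Mndal, Tmem87a, Ap1s3 and St6gal2. Without Gan replicate 1, 2 or 3 in turn, adjusted p was 0.095, 0.083 and 0.062 for Reg3b and 0.11, 0.13 and 0.11 for Reg1, and it was 0.14 for Reg3g without replicate 1 or 2. Gna14 differed by 0.34 ± 0.36 (0.73), Ptgs2 by 0.17 ± 0.66 (0.94), Ptges by 0.46 ± 0.26 (0.47) and Tnf by -0.05 ± 0.48 (0.98). Left out 1 at a time, Gan replicates 1, 2 and 3 gave 107, 74 and 118 called genes, and BALB/c replicates 1 and 2 gave 311 and 131.

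By camera 6 lists passed, all lower in BALB/c tumors, and 0 with an estimated correlation. By the rotation test fry the unadjusted p of these 6 ranged from 0.017 for parietal cell to 0.16 for macrophage genes. Of 12 antimicrobial genes 3 fell (camera adjusted p = 5.1e-04, or adjusted p = 0.80 with an estimated correlation). Of 9 parietal cell genes 1 fell, Kcnj15 at -1.59 ± 0.28 (3.7e-05 for the list, or adjusted p = 0.80 with an estimated correlation), and 5 passed when adjusted over the list alone. In the MHC class II list (0.0013, or adjusted p = 0.80 with an estimated correlation) 0 of 7 genes passed over all genes and 4 over the list alone, with H2-Aa at -2.04 ± 0.60 (0.14) and H2-Eb1 at -1.78 ± 0.52 (0.14). Strain differences in probe sequence, tested below only for genes called over all genes, were not tested for this list and stay open. In the mast cell list (0.0022, or adjusted p = 0.80 with an estimated correlation) 0 of 9 passed over all genes and 4 over the list alone, with the proteases Cpa3 at -2.40 ± 0.80 (0.19) and Mcpt1 at -2.37 ± 0.85 (0.22). The cytokine and chemokine list (0.0022, or adjusted p = 0.80 with an estimated correlation) and the macrophage list (0.011, or adjusted p = 0.80 with an estimated correlation) had 0 genes past the threshold over all genes or the list alone. Ccl20 was at -1 ± 0.35 (0.21), Ccl8 at -1.09 ± 0.39 (0.22), the complement gene C1qb at -1.38 ± 0.41 (0.15) and the macrophage receptor Adgre1 at -0.66 ± 0.25 (0.24). BALB/c replicate 1 stood apart in these immune lists, with a macrophage mean of 0.52 against -1.11 and -0.95, and without it 15 lists passed. Without that array the macrophage mean difference went from -0.70 to -1.22, the cytokine one from -0.68 to -1.12 and the antimicrobial one from -1.34 to -2.12. H2-Aa (-2.96, adjusted p = 0.00065), H2-Eb1 (-2.54, 0.0025), C1qb (-2.02, 0.001), Ccl20 (-1.48, 0.011) and Adgre1 (-0.96, 0.036) then passed. Without Gan replicate 1 the mast cell mean was -0.73 (0.03) and the antimicrobial mean -0.89 (0.012), and without BALB/c replicate 2 the latter was -0.87 (0.019). The macrophage call was lost without BALB/c replicate 2 (-0.40, 0.36) or replicate 3 (-0.48, 0.086), and the cytokine call without replicate 2 (-0.42, 0.24). The other 31 lists did not pass, with adjusted p from 0.0545, for chief cell genes at a mean of -1.62, to 0.93.

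Labelled-knockout and BALB/c tumors were also set against WT. There 4210 and 5394 genes were called by limma, 2150 and 2649 of them higher. With the added sex term the counts were 1192 and 1141. BALB/c tumors and WT differ in strain as well as in tumor.

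The design also allows a search for genes that were higher in Gan tumors than in WT and lower than in Gan tumors in both other tumor groups. By limma 0 genes met this at adjusted p values under 0.05. At an unadjusted p under 0.05 for both lower calls 46 genes did, and independent lists would give 32. In 100 simulations all arrays were redrawn with unchanged tumor groups that shared the simulated Gan arrays, which gave 29.5 on average, with a range of 18 to 41. Their noise was independent between genes, so that range is too narrow to judge the 46 by. Regroupings of the 9 real tumor arrays gave up to 422. The 46 became 26 without labelled-knockout replicate 2, 25 with averaged probe sets and 18 with the sex term, for which no simulations were run. Noxo1 was not among the genes lower in BALB/c tumors. Across genes, the log2 differences of labelled-knockout and BALB/c tumors from Gan tumors had a correlation of 0.0846 against a simulated 0.501, and a covariance of 0.0136 against a simulated 0.0428. Genes are not independent replicates, and with 3 Gan arrays these could not be parted into 2 sets of at least 2 arrays.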

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

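The tests of sex, of interferon genes and of genes on the chromosome of Tnf were chosen after the results were seen; the tests of scaling, of probe sequence and of other splits were planned. Outside the named genes, 501 of 5194 probe sets without a single gene symbol were higher in Gan tumors than in WT by limma, and 448 were lower, a signal in data that the comparisons do not use. Between labelled-knockout and Gan tumors 8 of these probe sets were called, 3 higher and 5 lower. Between BALB/c and Gan tumors 128 were called, 55 higher and 73 lower.

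The calls between Gan tumors and WT were set against scaling and sex. Scaling alone is argued against as the source of the calls: under quantile normalization 4741 genes were called and under median centring 5143, and 4356 and 3920 of these were among the 4639. The balance of directions did depend on scaling, as median centring took 2280 higher and 2359 lower calls to 3503 and 1640. The sex of the mice and the tumor cannot be told apart here, because only 1 tumor array has the sex of the WT mice. On that array the 1820 autosomal genes called with over a 2-fold difference lay at a median of 0.75 of the way from WT to Gan, with 99.4% on Gan's side, against 0.83 and 0.92 on the other labelled-knockout arrays. With a sex term their median log2 difference went from 1.58 to 1.43 and their median SE from 0.30 to 0.54, 1818 of 1820 kept their sign and 528 stayed called. The median SE thus grew more than the median difference shrank. The genes that lost their call were not looked at apart, and some, such as Pgc and Chia1, shrank by far more than the median.

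The interferon response genes that were higher in labelled-knockout than in Gan tumors do not rest on 1 array, as the highest camera adjusted p with an array left out was 9.6e-13. Sequence differences near Tnf could not act directly on these genes, since all 12 members that passed over the list alone lie on other chromosomes. That follows from which genes the list holds, and says nothing about an indirect effect. More macrophages as the cause of the whole rise are argued against, as their list differed by -0.12 ± 0.22 (SE over arrays), or -0.08 ± 0.23 without Cd14, which rose between WT and Gan, against 1.47 ± 0.06 for the interferon list. A small part from macrophages stays open (mean plus 2 SE 0.39 without Cd14), as do T and NK cells, with 4 genes at 0.67 ± 0.46, and, untested, an indirect effect of a gene near Tnf, a difference in housing or infection, and an effect of the knockout itself. With an estimated correlation the list did not pass (adjusted p = 0.41).

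The genes called between BALB/c and C57BL/6 tumors may in part reflect strain differences in probe sequence. Of 61 genes called lower that had other bright probe sets, these followed in the same direction by at least 50% of the difference for 57.4%, against 74.6% of 1133 genes called lower in Gan tumors than WT (Fisher's exact test, two-sided p = 0.0044). For genes called higher the shares were 51.9% of 52 and 63% of 1250 (Fisher's exact test, p = 0.11), which decides nothing. A mismatch with BALB/c sequence would be expected to act on the lower calls, and median sizes were not smaller in the BALB/c calls, 1.21 against 1.05 for lower calls. A true strain difference in expression stays open for each gene.

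Other splits of the arrays were also fitted, with 6 arrays in 2 groups of 3. There are 10 such splits, too few for a share under 0.05. The real split called 4317 genes for Gan against WT, 8 for labelled-knockout against Gan, 60 for BALB/c against Gan, 4332 for labelled-knockout against WT and 4397 for BALB/c against WT, and the highest other split called 1, 1, 1, 0 and 0, so 1 of 10 splits gave as many in each. For lists the real splits gave 14, 8 and 8 in the main comparisons and the highest others 19, 15 and 19, with 4, 7 and 4 of 10 splits giving as many. For genes higher in Gan than WT and lower in both other tumor groups, unadjusted p was used for the lower calls. Of 100 groupings of the 9 tumor arrays, the real one counted among them, 19 gave at least the real 46, up to 422, so chance is not excluded. A count that high points to structure among the tumor arrays, whose source was not tested.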

How the results depend on the processing

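The sex term and the renumbering were chosen after the data were seen; the other settings were planned. Beyond the settings given here, counts of called genes and of lists stayed within 1.5 times the main values. The cause of each move was not tested, except that a model with fewer arrays or an added term leaves fewer degrees of freedom. With an estimated camera correlation 0 lists passed in each comparison, against 11, 5 and 6. With the sex term the called genes fell to 698 (684 of them among the 4639) for Gan against WT, 1192 for labelled-knockout against WT and 1141 for BALB/c against WT. For labelled-knockout against Gan the 3 called genes became 12 with median centring, 16 with array weights, 8 with only the groups compared and 1 with the replicate block, and the 5 lists became 8 with median centring and 8 with only the groups compared. For BALB/c against Gan the 197 called genes became 311 with array weights and 60 with only the groups compared. Leaving out 1 array gave 3660 to 4155 genes for Gan against WT, 1 to 13 for labelled-knockout against Gan, 74 to 311 for BALB/c against Gan, 2923 to 3685 and 4534 to 5192 for the comparisons with WT, 10 to 13, 6 to 9 and 4 to 15 lists, and 0 to 0 genes for the search across the tumor groups. At unadjusted p the 46 genes of that search became 25 with averaged probe sets, 18 with the sex term and 26 without labelled-knockout replicate 2. Median centring took the median of all genes from -0.01 to 0.17 for Gan against WT, from 0 to 0.17 for labelled-knockout against WT and from -0.01 to 0.22 for BALB/c against WT, and the higher and lower calls from 2280 and 2359 to 3503 and 1640, from 2150 and 2060 to 3236 and 1373, and from 2649 and 2745 to 4420 and 1880; for labelled-knockout against Gan they went from 2 and 1 to 11 and 1, and for BALB/c against Gan from 100 and 97 to 114 and 83. The labels give replicate numbers but no shared animal, and the numbers were not taken to pair arrays: 8 of 18 same-numbered pairs had a correlation of deviations above 0.1 (range -0.2 to 0.3). Of 12 arrays 8 correlated best with their own number, where renumbering gives 4 on average and as many or more in 12 of 216 cases, a hint that does not settle it. With the replicate number as a block 4393, 1 and 138 genes were called in the main comparisons.

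Signs turned for Tnf between BALB/c and Gan (0.02 with quantile normalization, 0.10 with array weights, -0.49 to 0.24 with an array left out), Ptgs2 between BALB/c and Gan (-0.50 with averaged probe sets, -0.56 with array weights, -0.75 to 0.90 with an array left out), Ptgs2 between labelled-knockout and Gan (-0.06 with the sex term, -0.15 to 0.51 with an array left out), Ptges between labelled-knockout and Gan (0.15 with averaged probe sets, 0.07 with the sex term, -0.29 to 0.18 with an array left out), Mmut (0.14 with averaged probe sets), Muc4 (1.06 without probe sets matching several sequences) and Kdm5d between Gan and WT (-0.62 with the sex term). Of the named genes past the threshold, 38 of 72, 1 of 3 and 6 of 23 passed under every alternative run, and of the lists 7 of 11, 5 of 5 and 4 of 6 under every one but the estimated correlation. Dim genes such as Wnt1 are limited by signal over background. The RNA quality alternative was not run.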

Other observations

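The test on genes near Tnf and the sex term were chosen after the results were seen. Some lists that did not pass between Gan tumors and WT held genes that rose or fell by limma. Of 12 stem and progenitor genes 5 rose and 6 fell, and of 7 intestine genes 1 rose and 4 fell. The examples from the next 4 lists were chosen after their values were seen. Of 17 Wnt target genes 7 rose and 4 fell: Cd44, an adhesion receptor, by 4.11 ± 0.29 and Ascl2 by 2.10 ± 0.40 among those higher, with Tnfrsf19 at -3.53 ± 0.44 and Nkd1 at -2.07 ± 0.32. Of 9 prostaglandin genes 1 rose and 6 fell: the receptor Ptger4 rose by 2.49 ± 0.19, the receptor Ptger3 was at -3.56 ± 0.38 and prostacyclin synthase, Ptgis, at -4.30 ± 0.45. Of 9 mast cell genes 3 rose and 0 fell, the proteases Mcpt1, Mcpt2 and Mcpt4, by 3.27 ± 0.85, 3.00 ± 0.30 and 2.02 ± 0.40. Of 21 cytokine and chemokine genes 3 rose and 0 fell, among them the chemokines Ccl20 and Cxcl5 by 4.04 ± 0.35 and 4 ± 0.85. With the sex term Mcpt1 was at 0.13 (adjusted p = 0.97), Mcpt4 at 0.93 (0.48) and Nkd1 at -1.39 (0.19). Ascl2 at 2.02 (0.17) and Cxcl5 at 4.14 (0.18) differed about as much with that term as without it, but did not pass. Tnfrsf19 was at -0.98 (0.2) with a pseudocount at the 5th percentile, and Nkd1 at -0.71 (0.056) with averaged probe sets. Immediate early genes were high on 1 array, Gan replicate 3, with a list mean of 1.71 against -0.28 and -0.36 in the other Gan arrays.

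A hypothesis is that a segment around Tnf, carried along with the knockout, may account for part of the difference between labelled-knockout and Gan tumors. Leaving out genes of the interferon and MHC class II lists, 9 of 42 genes past an unadjusted p of 0.001 lie on the chromosome of Tnf, 21.4% against 4.9% of all genes (Fisher's exact test, two-sided p = 0.00016). The 9 were Pdia2, Glo1, H2-K1, Psmb9, Tap1, Tnf, Tubb5, Mmut and Guca1b, named after their values were seen. Tap1, Psmb9 and H2-K1 are known to respond to interferon, and Glo1 and Mmut, called by limma, prompted the test. Without Tap1, Psmb9, H2-K1 and Tnf 5 of 38 were on that chromosome (13.2%, Fisher's exact test, p = 0.035), and with the 3 called genes also left out 3 of 35 (8.6%, p = 0.24), so the hypothesis stays undecided. Glo1 (1.01 and 1.00) and Guca1b (-2.26 and -2.14) differed from Gan alike in labelled-knockout and BALB/c tumors, which share the Gan arrays as reference, and the other probe sets of Glo1 were also higher (0.53 to 1.19 in labelled-knockout tumors). H2-K1 (0.79 and -1.6), Psmb9 (1.95 and -0.26), Tap1 (1.64 and -0.6) and Tnf (2.33 and -0.05) did not differ alike. Tubb5 (0.48 and 0.17) and Mmut (-0.79 and -0.17) differed less in BALB/c tumors. The sources used here do not say which strain such a segment would come from, so likeness to BALB/c tumors takes no side. Pdia2 (2.80 in labelled-knockout, -2.53 in BALB/c tumors) fell by 5.93 between WT and Gan like the gland genes, which leaves another reading of its rise open. The other probe set of Mmut was at 0.13, which takes no side, since a sequence difference under a single probe set could also give it.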
